A study of Mus musculus with 25 samples.

How the data were processed

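Total RNA of mouse peritoneal macrophages of 6 genotypes was sequenced in 25 libraries, 5 of WT and 4 of each other genotype. Per the labels' protocols, RNA was purified with an RNeasy kit; whether the counting used strand is not given in the sources used here. The submitters' processing notes name STAR, Salmon, R 4.1.2 and DESeq2 with the builds GRCm38 and mm10, without roles. The labels' extract protocol instead names pBWA 0.5.9-r32-MPI-patch2, bedtools 2.16.2 and Ensembl Gene 61. These accounts differ, and which of them made the values is not given in the sources used here. The rule that left 13266 genes in the table is likewise not stated. Of these, 1007 had no symbol and 30 shared a symbol with another.

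The deposited values per library are on a log2 scale, made by the authors with the variance-stabilizing transformation of DESeq2 from counts divided by size factors, as the values themselves show. They share a floor of 5.81, the value of a count of 0. The signal per genotype, named by the file headers as group means and baseMean, is the mean of those normalized counts over a genotype or over all libraries, as the authors deposited it. Log2 fold changes, p-values and adjusted p-values of 7 comparisons were deposited by the authors, per the file headers, and are used here only for comparison. Of the other sheets, both repeated part of the first table and were not used.

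Normalized counts were recovered by inverting the transformation with 1 fitted constant (0.252). The means of the recovered values differed from the deposited group means by at most 3.84e-14, and 100% of them were whole reads at a tolerance of 0.01 once divided by the value of 1 read in their library. The listed genes held between 25886469 and 39590589 reads per library, which is the depth behind each value. No library pair within a genotype was a duplicate (chi-square per degree of freedom between replicates from 13.6 to 217.5). Libraries were assigned to genotypes by the start of their column names and numbered in column order. Titles of SAMHD1 KO samples use different names for the line, and columns could not be matched to single titles.

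The design, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The design assumed counts for the test. Because the values per library were normalized, its stated fallback was used: limma 3.58.1 (trend and robust, R 4.3.3, statmod 1.5.0) on log2 of normalized count + 1, with all 25 libraries in 1 fit, genotype as the only factor, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Genes needed a normalized count of at least 10 in at least 4 libraries, which kept 13252 and left out 14. Added to every count, the 1 makes fold changes of low genes smaller than they are. The comparisons were each single knockout against WT, each double knockout against SAMHD1 KO and against its sensor knockout, both double knockouts against each other, and the interactions of SAMHD1 with MDA5 and with RIG-I. Errors of log2 fold changes are standard errors. Fold changes are differences of mean log2 values and need not equal the ratio of the mean counts printed beside them.

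Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 20 lists per comparison, and again with an estimated correlation; fry, a self-contained rotation test, was run beside it. Of the lists that passed with the preset correlation, those that held with the estimated one were the interferon-stimulated genes in the 3 comparisons of SAMHD1 loss and the neutrophil and eosinophil markers between the double knockouts. Measured members were 44 of 44 interferon-stimulated genes, 15 of 15 interferon-inducible GTPases, 15 of 15 MHC class I, 9 of 10 MHC class II, 4 of 11 chemokines, 4 of 11 interferons and receptors, 24 of 24 nucleic acid sensing, 16 of 19 inflammatory, 17 of 20 p53, 24 of 24 proliferation, 18 of 18 dNTP metabolism and 13 of 13 dissociation genes. For cell types they were 15 of 15 large and 12 of 13 small peritoneal macrophage, 10 of 12 B cell, 6 of 11 T cell, 5 of 8 mast cell, 4 of 10 neutrophil and eosinophil, 3 of 8 dendritic cell and 4 of 5 erythroid genes. Sex-linked genes (1 of 5, Xist, at 0.60 ± 0.42 in SAMHD1 KO against WT, adjusted p = 0.965) and the targeted genes were not tested as lists. A list's score is the mean of its members' log2 values in a library. Scores of interferon-stimulated genes were compared by exact two-sided permutation, adjusted over 6 comparisons; with 4 libraries against 4 the smallest possible p is 0.0286.

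The text names Samhd1, Ifih1 and Ddx58 in each comparison. It names the 10 genes up and the 10 down with the smallest p among called genes of at least 2-fold with a symbol in SAMHD1 KO against WT and in both double knockouts against each of their single knockouts, and 5 up and 5 down elsewhere, filled with called genes of any size. It also names up to 4 members of a described list that passed, or, where none did, up to 2 of its most abundant members. Genes known only by a Gm or Rik name are counted. A few genes that the rule names are not reported here. Coordinates are from GENCODE M21 (GRCm38), matched by Ensembl identifier for 13259 genes and not matched for 7, with the same symbol for 90.1%. Dynlt1b, Ifit3 and Ifit3b, Ifi206 and the Oas and Gbp families have near copies between which reads may have been split.

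The limma steps were tested on simulated data made from the real means and library sizes. In these, 200 random genes and a list of 44 other random genes, of 13252, were changed. Reads were drawn separately for each gene, so the list lacked the correlation between real interferon-stimulated genes. With so many genes changed, an adjusted p under 0.05 is also easier to reach than where few genes change. For SAMHD1 KO against WT, 46.3% of 1.5-fold, 70.1% of 2-fold and 92.4% of 4-fold changes were recovered, with 12 calls among 13008 unchanged genes. Other settings fixed at the start were quantile normalization, no low-count filter, a pseudocount of 0.1, fits of only the compared genotypes, a threshold of 0.1, the authors' comparisons, an estimated correlation, fry, the median over members, and leaving out each library. Chosen after the data were seen were the variance-stabilized values as deposited, voom on the recovered reads, fits without 2 doubted pairs of libraries, and every list with each library left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for recovery of counts and for figures.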

Results

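RNA-seq was performed on peritoneal macrophages of untreated mice of 6 genotypes, at Day 0 of the labels. WT mice gave 5 libraries. SAMHD1 KO, MDA5 KO, RIG-I KO, SAMHD1 MDA5 DKO and SAMHD1 RIG-I DKO mice gave 4 libraries each. SAMHD1 is a deoxynucleotide triphosphohydrolase whose loss raises interferon signalling. MDA5, encoded by Ifih1, and RIG-I, encoded by Ddx58, are cytosolic sensors of RNA. The design asks whether the response to SAMHD1 loss needs either sensor. The listed genes held between 25886469 and 39590589 reads per library, the 10 most abundant genes took 16 to 19.2% of them, and 37 to 82 of 13266 genes were at 0 in a library. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these samples. Libraries are numbered within a genotype in column order, which is a name only and not the number in a sample title.

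WT library 3 and SAMHD1 KO library 2 stood apart from the rest on the first principal component (20.3% of the variance), at -50.89 and -63.93, with the other libraries between -20.69 and 25.76. The same libraries carry the last 2 of the 25 library codes in the column names, while the codes of the other libraries follow one another within each genotype. What the code stands for is not stated. Each comparison that used either library was therefore repeated without both, within the main run of codes. The 2 libraries hold 1 WT and 1 SAMHD1 KO sample, too few for a value of their own.

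The targeted genes were examined first, with coordinates from GRCm38. Samhd1 (ENSMUSG00000027639, chromosome 2, 157097533 to 157135265) had 9904 ± 2290 normalized counts in WT (SD, n = 5), 10780 ± 1640 in MDA5 KO and 9923 ± 964 in RIG-I KO (n = 4 each). It had 2186 ± 1730 in SAMHD1 KO, 2194 ± 1840 in SAMHD1 MDA5 DKO and 1633 ± 149 in SAMHD1 RIG-I DKO. Of the libraries labelled SAMHD1 KO, library 2 kept 4767 counts, 48.1% of the WT mean, and of those labelled SAMHD1 MDA5 DKO, library 3 kept 4952, 50% of it. The other SAMHD1 KO libraries had 1113, 1566 and 1299. Ifih1 (ENSMUSG00000026896, chromosome 2, 62595798 to 62646255) fell to 5.53 ± 6.58 in MDA5 KO and 7.31 ± 4.66 in SAMHD1 MDA5 DKO, against 1804 ± 152 in WT, 2025 ± 313 in SAMHD1 KO, 1541 ± 152 in RIG-I KO and 2002 ± 221 in SAMHD1 RIG-I DKO. Ddx58 (ENSMUSG00000040296, chromosome 4, 40203773 to 40239828) fell to 202.2 ± 7.36 in RIG-I KO and 263.8 ± 38.3 in SAMHD1 RIG-I DKO, against 1536 ± 204 in WT, 1982 ± 241 in SAMHD1 KO, 1270 ± 145 in MDA5 KO and 1396 ± 147 in SAMHD1 MDA5 DKO. Each direction below that rests on SAMHD1 loss includes these 2 libraries of intermediate Samhd1 unless stated.

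**Figure D1:**
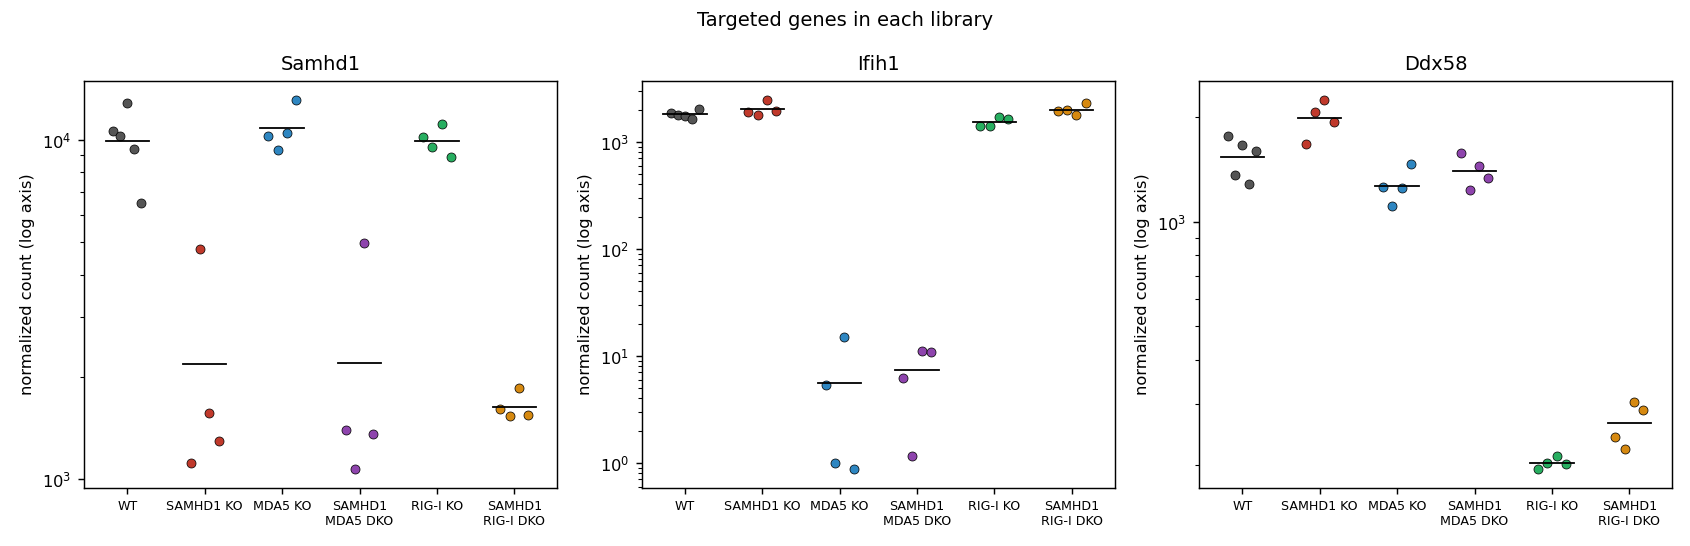
Normalized counts (logarithmic axis) of Samhd1, Ifih1 and Ddx58, with 1 point per library, grouped by genotype, and a line at the group mean. SAMHD1 KO library 2 (4767) and SAMHD1 MDA5 DKO library 3 (4952) lie between the WT mean of 9904 and the other libraries of their genotypes for Samhd1.

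With both sensors present, loss of SAMHD1 raised Irf7, the transcription factor that amplifies type I interferon production. It rose 2.47-fold, from 1780 ± 465 normalized counts in WT (SD, n = 5) to 4402 ± 1290 in SAMHD1 KO (n = 4), a log2 fold change of 1.30 ± 0.21 (SE, limma adjusted p = 0.015). Samhd1 fell 5.33-fold (-2.42 ± 0.36, adjusted p = 0.014). These were the 2 genes called among 13252 tested. Ifih1 (0.16 ± 0.47, adjusted p = 0.98) and Ddx58 (0.37 ± 0.11, adjusted p = 0.64) did not pass.

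The interferon-stimulated genes rose as a group in SAMHD1 KO against WT. Of 44 members, 43 had a positive log2 fold change, with a median of 0.545, and 31 were higher when adjusted over the list alone, against 1 over all genes; leaving out 1 library gave 26 to 35. The members that passed ran from Irf9 at 0.24 to Ifi44 at 2.11. Among them, Oasl1, which restrains translation of Irf7, had a log2 fold change of 1.74 ± 0.32 (adjusted p over the list alone 0.00039), the nuclear body protein Sp100 0.53 ± 0.10 (0.00047) and Phf11d 0.72 ± 0.16 (0.0013). The list passed camera (adjusted p = 2.92e-44) and held with an adjusted p = 0.0209 with an estimated correlation. Its score per library was 10.09 ± 0.24 in SAMHD1 KO and 9.41 ± 0.31 in WT, and all 4 SAMHD1 KO libraries lay above all 5 WT libraries (difference 0.69, exact two-sided permutation p = 0.00794, adjusted p = 0.0476, and 0.00794 is the smallest p this design allows).

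Other groups moved less firmly in SAMHD1 KO. Dissociation and immediate early genes were higher in 13 of 13 members (median 0.397, adjusted p = 0.000262, adjusted p = 0.117 with an estimated correlation), though Dusp1 (0.13 ± 0.59) and Junb (0.35 ± 0.28) did not pass alone. All 24 proliferation genes had negative values (median -0.607, adjusted p = 5.01e-05, adjusted p = 0.57 with an estimated correlation), with Pcna at -0.12 ± 0.14 and Mcm6 at -0.42 ± 0.27. Mast cell markers had a median of 1.58 (adjusted p = 0.000133, adjusted p = 0.276 with an estimated correlation), with the tryptase Tpsb2 at 1.89 ± 0.75 and the protease Mcpt4 at 1.75 ± 0.79. MHC class II genes had a median of -0.294 (adjusted p = 0.0163, adjusted p = 0.57 with an estimated correlation), with Cd74 at -0.69 ± 0.59 and Ctss at -0.01 ± 0.14. Interferon-inducible GTPases had a median of 0.287 (adjusted p = 0.0189, adjusted p = 0.693 with an estimated correlation), and large peritoneal macrophage markers -0.0818 (adjusted p = 0.0189, adjusted p = 0.387 with an estimated correlation). Of these lists, dissociation genes alone kept their call whichever library was left out, with a median of 0.225 without SAMHD1 KO library 2 and 0.641 without WT library 3, the libraries apart on the first component. Of the nucleic acid sensing list, which did not pass as a set (adjusted p = 0.206), the RNA editor Adar (0.32 ± 0.08), the exonuclease Trex1 (0.33 ± 0.10) and Ifi204 (0.38 ± 0.11) were higher when adjusted over the list alone.

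Within the main run of library codes, 1 gene was called in SAMHD1 KO against WT, Samhd1, while Irf7 had 1.44 with an adjusted p = 0.0583; the interferon-stimulated list had a median of 0.565 (adjusted p = 2.69e-45) and its score a difference of 0.74 (exact permutation p = 0.0286). Neither gene was called in a fit of these 2 genotypes alone or without SAMHD1 KO library 3, SAMHD1 KO library 4 or WT library 2, nor Irf7 without WT library 4.

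**Figure D2:**
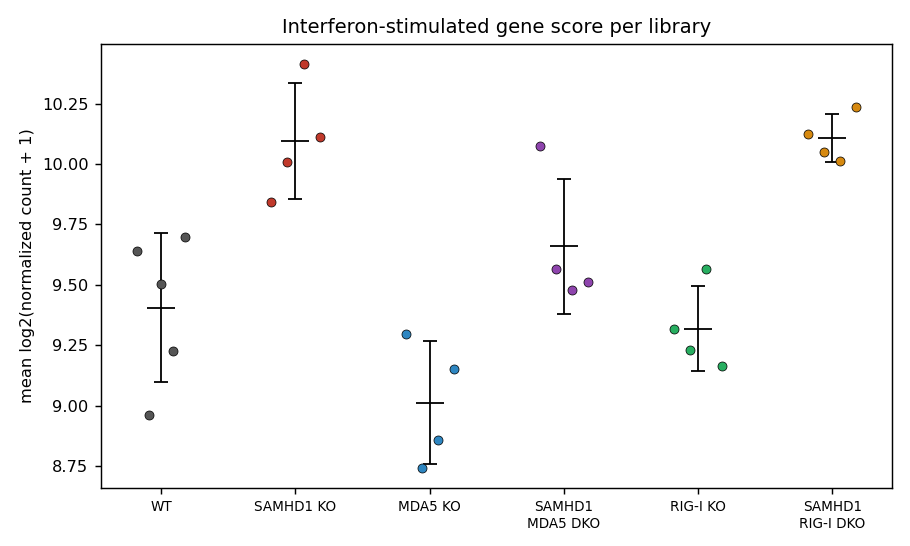
Interferon-stimulated gene score (mean log2 of normalized count + 1 over 44 genes), with 1 point per library, grouped by genotype, and bars for mean ± SD. SAMHD1 KO (10.09 ± 0.24) and SAMHD1 RIG-I DKO (10.11 ± 0.10) lie above WT (9.41 ± 0.31), and MDA5 KO (9.01 ± 0.26) has the lowest mean.

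Where MDA5 was absent, loss of SAMHD1 again went with higher interferon-stimulated genes (SAMHD1 MDA5 DKO against MDA5 KO, n = 4 each). Of the 44 members, 43 had positive values, with a median of 0.453, and 21 were higher when adjusted over the list alone, against 0 over all genes. That count was 10 without SAMHD1 MDA5 DKO library 1 or MDA5 KO library 2, 11 without MDA5 KO library 3 and at most 26 without any other. They ran from Trim30a at 0.29 to Ifi44 at 2.73 ± 0.55, with Oasl1 at 1.89 ± 0.34, the deubiquitinase-like Usp18 at 1.01 ± 0.24 and the antiviral Ifit3 at 1.35 ± 0.34. Ifit3 may share reads with its near copy Ifit3b. The list passed camera (adjusted p = 3.23e-39, adjusted p = 0.0354 with an estimated correlation). The score was 9.66 ± 0.28 in SAMHD1 MDA5 DKO and 9.01 ± 0.26 in MDA5 KO, with all 4 libraries above all 4 (difference 0.65, exact two-sided permutation p = 0.0286, the smallest possible, adjusted p = 0.0571).

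Interferon-inducible GTPases, which defend the cytosol against pathogens, were positive in 15 of 15 members in the same comparison (median 0.615, adjusted p = 8.41e-14, adjusted p = 0.159 with an estimated correlation). Of them, 7 were higher when adjusted over the list alone, against 0 over all genes, including Iigp1 (1.4 ± 0.47), Igtp (0.61 ± 0.23), Ifi47 (0.73 ± 0.28) and Gbp3 (0.35 ± 0.14). The GTPase score was 11.002 in SAMHD1 MDA5 DKO library 1 and 9.0017, 9.1027 and 8.9924 in the other libraries of the genotype, and without library 1 the list passed with a median of 0.226 (adjusted p = 0.000338). MHC class I genes had a median of 0.259 (adjusted p = 4.7e-05, adjusted p = 0.313 with an estimated correlation), with H2-D1 at 0.19 ± 0.16 and H2-K1 at 0.23 ± 0.19. MHC class II genes had 0.579 (adjusted p = 0.00839, adjusted p = 0.383 with an estimated correlation), with Cd74 at 0.74 ± 0.62. Without the same library the median was 0.0667 for MHC class I (adjusted p = 0.584) and 0.00685 for MHC class II genes, whose mean was -0.0223 and which camera put down (adjusted p = 0.905). All 4 measured chemokines were positive (median 1.03, adjusted p = 0.0078, adjusted p = 0.0534 with an estimated correlation), with Cxcl16 at 0.24 ± 0.18 and Ccl3 at 0.85 ± 0.70; without MDA5 KO library 4 the median was 0.649. B cell markers (median -0.881, adjusted p = 0.00118), mast cell markers (-1.02, adjusted p = 0.00791), large peritoneal macrophage markers (-0.155, adjusted p = 0.00791), genes of dNTP metabolism (0.0945, adjusted p = 0.0133) and dissociation genes (0.279, adjusted p = 0.0348) also passed camera, each with an adjusted p = 0.313 with an estimated correlation, and all but mast cell markers lost their call when 1 or more libraries were left out in turn. Ltbp1 (-0.39 ± 0.12) fell and, of the small macrophage and monocyte markers, Plac8 (2.49 ± 0.80) rose and Mgl2 (-0.87 ± 0.28) fell when adjusted over their lists alone.

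Over all genes, limma called 1 gene, Samhd1, which fell 6-fold (-2.59 ± 0.38, adjusted p = 0.011), with 525 genes at an unadjusted p under 0.05 against 663 by chance, and voom also called 1. Ifih1 (0.64 ± 0.50) and Ddx58 (0.14) did not pass. Without the 2 libraries of intermediate Samhd1 the count was 9, and in a fit of these 2 genotypes alone it was 0.

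Where RIG-I was absent, the genes that rose with SAMHD1 loss were mostly interferon-stimulated (SAMHD1 RIG-I DKO against RIG-I KO, n = 4 each). Ifi44 rose from 8.08 ± 7.84 to 77.8 ± 22.4 normalized counts (log2 fold change 3.54 ± 0.55, adjusted p = 0.0087). Oasl1 rose from 49.6 ± 14.4 to 186.8 ± 33.5 (1.91 ± 0.34, adjusted p = 0.023), Irf7 by 1.23 ± 0.22 on the log2 scale (adjusted p = 0.023) and the antiviral Rsad2 by 1.52 ± 0.29 (adjusted p = 0.049). Ifi206, whose reads may be split among its gene family, rose 5.25-fold (2.39 ± 0.44, adjusted p = 0.027). The sorting receptor Sorl1 (1.22 ± 0.20, adjusted p = 0.012) and the phosphodiesterase Pde7b (1.15 ± 0.21, adjusted p = 0.025) rose as well. Samhd1 fell 6.07-fold (-2.60 ± 0.38, adjusted p = 0.0087), for 9 called genes in all, 8 higher and 1 lower. Of 14 alternative runs, the call was lost in 1 for Samhd1, 2 for Ifi44, 5 for Sorl1, 7 each for Oasl1, Irf7 and Pde7b, 8 for Ifi206 and 10 for Rsad2. Ifih1 (0.38) and Ddx58 (0.37 ± 0.12, adjusted p = 0.59) did not pass.

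All 44 interferon-stimulated genes were positive in SAMHD1 RIG-I DKO against RIG-I KO, with a median of 0.521, from Irf9 at 0.23 to Ifi44 among those that passed. Of them, 32 were higher when adjusted over the list alone, against 4 over all genes; leaving out 1 library gave 23 to 34. The list passed camera (adjusted p = 6.11e-65, adjusted p = 0.00314 with an estimated correlation). Its score was 10.11 ± 0.10 against 9.32 ± 0.18 (difference 0.79, exact two-sided permutation p = 0.0286, the smallest possible, adjusted p = 0.0571). GTPases had a median of 0.499 (adjusted p = 2.79e-07, adjusted p = 0.458 with an estimated correlation), with Gbp2 at 0.13 ± 0.25. MHC class I genes had 0.254 (adjusted p = 1.06e-05, adjusted p = 0.458 with an estimated correlation), with H2-D1 at 0.28 ± 0.16 and H2-K1 at 0.30 ± 0.19. Nucleic acid sensing genes passed (median 0.0667, adjusted p = 0.000663, adjusted p = 0.051 with an estimated correlation), with Adar (0.38 ± 0.09), Trex1 (0.39 ± 0.10) and Ifi204 (0.39 ± 0.12) higher when adjusted over the list alone. Proliferation (0.374, adjusted p = 0.0123, adjusted p = 0.957 with an estimated correlation), dNTP metabolism (0.118, adjusted p = 0.04, adjusted p = 0.701 with an estimated correlation) and p53 target genes (-0.0267, adjusted p = 0.0463, adjusted p = 0.127 with an estimated correlation) passed camera too, and each lost its call when 1 of several libraries was left out. Plac8 (3.02 ± 0.80) rose when adjusted over its list alone. A fit of these 2 genotypes alone called 68 genes, and leaving out 1 library gave between 0 and 10. The fit of all 25 libraries shares 1 variance per gene with WT, whose replicates differed more than those of RIG-I KO. That variance may be too large for this comparison, which was not tested.

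**Figure D3:**
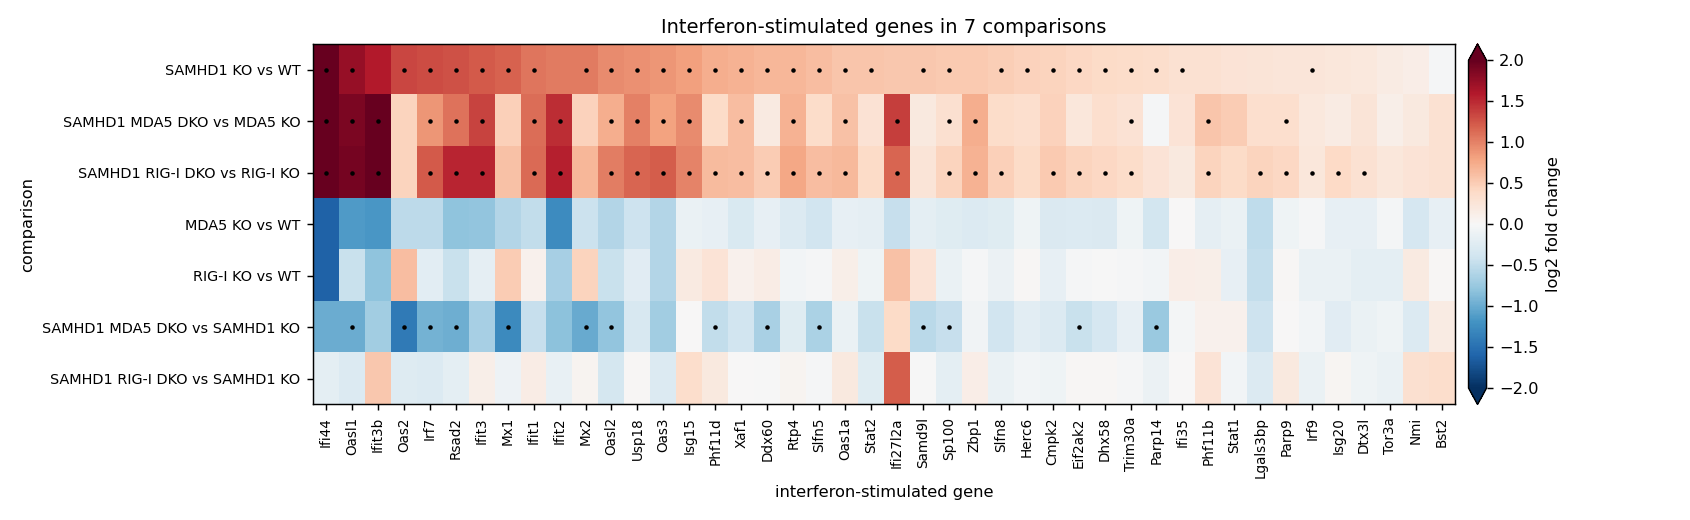
Log2 fold changes (colour, limited to 2 in either direction) of 44 interferon-stimulated genes in 7 comparisons, with dots where a gene passed when adjusted over the list alone. SAMHD1 loss gave 31, 21 and 32 higher members in WT, MDA5 KO and RIG-I KO backgrounds.

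The comparisons of SAMHD1 loss share no library, and their fold changes had the same sign for 42 of 44 interferon-stimulated genes between SAMHD1 KO against WT and SAMHD1 MDA5 DKO against MDA5 KO. The same held for 43 of 44 between SAMHD1 KO against WT and SAMHD1 RIG-I DKO against RIG-I KO. Higher in all 3 when adjusted over the list alone were 15 members, and 40 were higher in any. Irf7 was called higher in WT and RIG-I KO backgrounds, where independent lists would share 0.000604 genes.

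Whether the effect of SAMHD1 loss differed with a sensor was tested by interaction. For MDA5, limma called 0 genes (smallest adjusted p = 0.98, 368 at an unadjusted p under 0.05 against 663 by chance, voom 0). For RIG-I it also called 0 (smallest adjusted p = 1, 375 at an unadjusted p under 0.05, voom 0). Samhd1 had interaction terms of -0.17 ± 0.53 with MDA5 and -0.19 with RIG-I, Ifih1 0.48 ± 0.69 and 0.22, and Ddx58 -0.23 ± 0.16 and 0.00. The interferon-stimulated list had a median of -0.0426 with MDA5 (adjusted p = 0.528, adjusted p = 0.908 with an estimated correlation) and 0.0808 with RIG-I (adjusted p = 0.24, adjusted p = 0.947 with an estimated correlation). For its score the terms were -0.04 ± 0.24 (SE) and 0.10 ± 0.24. Mast cell markers had a negative term with MDA5 (median -2.78, adjusted p = 2.04e-06, adjusted p = 0.171 with an estimated correlation), with Cma1 at -2.78 ± 1.01, Tpsb2 -2.91 ± 1.09, Kit -2.41 ± 0.95 and Mcpt4 -2.75 ± 1.15. Both counts stayed at 0 within the main run of codes, and the list had adjusted p = 0.119 with MDA5 and 0.864 with RIG-I. The list passed for MDA5 when SAMHD1 MDA5 DKO library 1 (adjusted p = 0.00073), SAMHD1 KO library 1 (0.0348) or MDA5 KO library 2 (0.0397) was left out, and for RIG-I when WT library 2 (0.00371), SAMHD1 KO library 3 (0.00403) or RIG-I KO library 3 (0.0126) was. SAMHD1 MDA5 DKO library 1 had a high score for its genotype (10.08, nearest 9.567). Without it, the score difference with SAMHD1 loss was 0.508 in the MDA5 KO background, against 0.69 in WT. The result for MDA5 thus depends on single libraries. In simulated data for the MDA5 term, 29.9% of 1.5-fold, 56.7% of 2-fold and 86.4% of 4-fold changes were recovered.

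Interferon-stimulated genes were lower in SAMHD1 MDA5 DKO than in SAMHD1 KO (n = 4 each), but this held neither with an estimated correlation nor in the score. Of 44 members, 39 had negative values, with a median of -0.407, and 14 were lower when adjusted over the list alone, against 0 over all genes. That count was 27 without SAMHD1 MDA5 DKO library 1, 4 without library 2 and 5 without library 3 of that genotype or library 3 of SAMHD1 KO. They ran from Oas2 at -1.41 to Eif2ak2, the RNA-activated kinase, at -0.45, with Parp14 at -0.74 ± 0.16, Irf7 at -0.94 ± 0.22, Sp100 at -0.46 ± 0.11 and Slfn5 at -0.63 ± 0.16. The list passed camera (adjusted p = 1.84e-07) and was lost with an adjusted p = 0.674 with an estimated correlation. The score differed by -0.44, with 3 of 4 libraries below all SAMHD1 KO libraries, and did not pass (exact two-sided permutation p = 0.0857, adjusted p = 0.103).

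Over all genes, 16 passed in SAMHD1 MDA5 DKO against SAMHD1 KO, 7 higher and 9 lower. Of the 15 other than Ifih1, 6 lay within 20 Mb of it, where 0.128 were expected. Rnd3, Kif5c, Fap, Gca and Cytip are among them, and a direct effect of MDA5 loss on these was not tested. Ifih1 fell by 8.19 ± 0.50 on the log2 scale (adjusted p = 8.6e-10). The kinesin heavy chain Kif5c (-4.28 ± 0.44, adjusted p = 6.8e-06), the serine protease Fap (-3.81 ± 0.63, adjusted p = 0.0067), Fxyd6 (-3.00 ± 0.59, adjusted p = 0.034) and the calcium-binding Gca (-1.14 ± 0.18, adjusted p = 0.0062) fell. So did the flippase Atp8b2 (-0.91 ± 0.17, adjusted p = 0.028) and the cytohesin partner Cytip (-0.46 ± 0.08, adjusted p = 0.0067). Rnd3 rose (2.06 ± 0.20, adjusted p = 4.2e-06), as did the dynein light chain Dynlt1b (1.46 ± 0.18, adjusted p = 0.00017), whose near copies may share its reads. Glmn (0.62 ± 0.12, adjusted p = 0.028) and the mitochondrial ribosomal Mrpl21 (0.61 ± 0.12, adjusted p = 0.039) and Mrps14 (0.60 ± 0.12, adjusted p = 0.045) rose. Ifih1, Rnd3, Dynlt1b and Kif5c kept their calls in all 17 alternative runs, while Cytip lost it in 1, Gca in 2, Fap in 4, Glmn in 7, Mrpl21, Mrps14 and Atp8b2 in 8 and Fxyd6 in 10. Fold changes fell with transcript length (Spearman correlation -0.369), and 10 of the 16 genes were still called with that trend removed. Samhd1 (-0.03, adjusted p = 0.97) and Ddx58 (-0.50 ± 0.12, adjusted p = 0.07) did not pass.

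Mast cell markers were lower in the same comparison, 5 of 5 when adjusted over the list alone (median -2.12, adjusted p = 0.00703, adjusted p = 0.674 with an estimated correlation), with Cma1 at -2.28 ± 0.73, Kit -1.96 ± 0.69, Tpsb2 -2.18 ± 0.79 and Mcpt4 -1.97 ± 0.83, and the list did not pass without SAMHD1 KO library 4 (adjusted p = 0.113). Genes of dNTP metabolism had a median of 0.308 (adjusted p = 0.00703, adjusted p = 0.674 with an estimated correlation), with Ada (0.75 ± 0.20) and Nt5c (0.52 ± 0.16) higher when adjusted over the list alone. MHC class I genes (median 0.105, adjusted p = 0.0366) and MHC class II genes (0.645, adjusted p = 0.00703) each had an adjusted p = 0.691 with an estimated correlation. Without SAMHD1 MDA5 DKO library 1 neither passed, at -0.0199 (adjusted p = 0.902) and 0.361 (adjusted p = 0.139). The proteasome subunits Psme2 (0.70 ± 0.18), Psme1 (0.42), Psmb8 (0.55 ± 0.19) and Psmb9 (0.51 ± 0.19) were higher when adjusted over the MHC class I list alone, and Cd74 had 1.24 ± 0.62. Of the other lists, Adar (-0.34 ± 0.09), Flt3 (-2.05 ± 0.73) and Zbtb46 (-0.42 ± 0.17) were lower and Rnaseh2c (0.60 ± 0.16) and Rnaseh2a (0.32 ± 0.10) higher when adjusted over their lists alone. Within the main run of library codes 534 genes were called, 446 higher and 88 lower, the 16 among them, and the interferon-stimulated list had an adjusted p = 2.4e-10 and a score difference of -0.46 (exact permutation p = 0.0857). Without the 2 libraries of intermediate Samhd1 6 genes were called, and an adjusted p under 0.1 gave 932.

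Loss of RIG-I in macrophages without SAMHD1 gave no difference in interferon-stimulated genes that passed a test (SAMHD1 RIG-I DKO against SAMHD1 KO, n = 4 each). Their median was -0.022 and their mean 0.0128, and camera put them up (adjusted p = 0.779, adjusted p = 0.935 with an estimated correlation), so median differed in sign from mean and test. The score differed by 0.01 (exact two-sided permutation p = 0.886), with a model standard error of 0.17. The list had an adjusted p = 0.995 within the main run of codes and the score a difference of -0.02 (exact permutation p = 0.971).

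In contrast, 1388 genes passed in this comparison, 745 higher and 643 lower, with 86 and 91 of them at least 2-fold. Leaving out 1 library gave 188 to 1418, with 44 higher and 144 lower without SAMHD1 RIG-I DKO library 2 and 147 and 384 without SAMHD1 KO library 2. The chemokine receptor of follicular lymphocytes Cxcr5 fell from 163.9 ± 173 normalized counts to 0.511 ± 0.606 (-6.18 ± 0.81, adjusted p = 0.00068). The B cell transcription factor Pax5 fell from 107.3 ± 110 to 1.12 ± 0.883 (-5.16 ± 0.76, adjusted p = 0.0018) and the tryptase Tpsb2 from 130.3 ± 164 to 0.85 ± 1.70 (-5.72 ± 0.79, adjusted p = 0.0011). Spib (-4.75 ± 0.72, adjusted p = 0.002), Dtx1 (-4.37 ± 0.62, adjusted p = 0.0012), the mast cell chymase Cma1 (-4.78 ± 0.73, adjusted p = 0.002), the lymphocyte GTPase Gimap4 (-3.09 ± 0.49, adjusted p = 0.0031) and Zfp831 (-3.63 ± 0.61, adjusted p = 0.0036) fell too. Ddx58 fell by 2.91 ± 0.12 on the log2 scale (adjusted p = 5.8e-14), while Samhd1 (-0.15) and Ifih1 (-0.01) did not pass.

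Among the genes that rose were the centromere protein gene Itgb3bp (1.13 ± 0.19, adjusted p = 0.0036), the proteasome assembly factor Psmg4 (1.10 ± 0.21, adjusted p = 0.0074), the respiratory chain gene Ndufb1 (1.23 ± 0.25, adjusted p = 0.0094) and Pet100, an assembly factor of cytochrome oxidase (1.10 ± 0.24, adjusted p = 0.013). The short noncoding RNA Bc1 rose 5.33-fold (2.41 ± 0.48, adjusted p = 0.0094). Smim4 (1.05 ± 0.21), Rpl27-ps3 (1.21 ± 0.26), Syce2 (1.57 ± 0.34), Gng10 (1.02 ± 0.23) and Serpinb7 (1.41 ± 0.33) rose as well. Reads of the pseudogene Rpl27-ps3 may come from its parent gene. Fold changes in this comparison fell with transcript length (Spearman correlation -0.2975).

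By group, B cell markers fell in SAMHD1 RIG-I DKO against SAMHD1 KO (median -3.84, adjusted p = 4.22e-08, adjusted p = 0.21 with an estimated correlation), 9 of 10 when adjusted over the list alone and 8 over all genes, with Ighm at -4.76 ± 0.79 and Ebf1 -4.11 ± 0.82. All 5 mast cell markers fell in both counts (median -4.78, adjusted p = 8.8e-08, adjusted p = 0.0823 with an estimated correlation), with Mcpt4 at -4.99 ± 0.83 and Kit -4.04 ± 0.69. T cell markers had a median of -1.55 (adjusted p = 0.00898, adjusted p = 0.421 with an estimated correlation), 5 lower when adjusted over the list alone and 1 over all genes, with Tcf7 at -2.37 ± 0.59. Dendritic cell markers had -2.53 (adjusted p = 0.00939, adjusted p = 0.0823 with an estimated correlation), with Ccr7 (-3.64 ± 0.68) and Flt3 (-2.53 ± 0.73) lower. Genes of dNTP metabolism rose (median 0.397, adjusted p = 0.00035, adjusted p = 0.252 with an estimated correlation), 8 when adjusted over the list alone and 1 over all genes, with Nme2 at 1.22 ± 0.36, Nme1 0.57 ± 0.18 and Ada 0.61 ± 0.20. Proliferation genes had a median of 0.664 (adjusted p = 0.00939, adjusted p = 0.864 with an estimated correlation), with Pcna at 0.54 ± 0.15, and lost the call without SAMHD1 KO library 1 (adjusted p = 0.197). Psme2 (0.73 ± 0.18), S100a8 (1.02 ± 0.31) and Rnaseh2a (0.33 ± 0.10) were higher and Selp (-0.33 ± 0.09) lower when adjusted over their lists alone. Within the main run of library codes 2122 genes were called, 1231 of them shared, and without the 2 libraries of intermediate Samhd1 548, 441 of them shared.

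Both double knockouts were then compared directly (SAMHD1 MDA5 DKO against SAMHD1 RIG-I DKO, n = 4 each). Interferon-stimulated genes were lower without MDA5 than without RIG-I, negative in 41 of 44 members (median -0.374), with 7 lower when adjusted over the list alone (3 to 21 with 1 library left out), from Phf11d at -0.69 ± 0.17 to Eif2ak2 at -0.47, and with Nmi at -0.60 ± 0.13, Parp14 -0.62 ± 0.16 and Slfn5 -0.60 ± 0.16. The list passed camera (adjusted p = 2.62e-15, adjusted p = 0.146 with an estimated correlation). The score difference of -0.45, with 3 of 4 libraries below all others, did not pass (exact two-sided permutation p = 0.0857, adjusted p = 0.103). Of 21 called genes, 14 were higher, among them Ddx58 (2.40 ± 0.12, adjusted p = 3.8e-12), Rnd3 (2.61 ± 0.20, adjusted p = 2.9e-08), Cxcr5 (5.14 ± 0.81, adjusted p = 0.0035), Dtx1 (3.22 ± 0.62, adjusted p = 0.027) and Gimap3 (2.25 ± 0.45, adjusted p = 0.037). Lower were Ifih1 (-8.18, adjusted p = 4.4e-10), Kif5c (-4.10 ± 0.44, adjusted p = 1.1e-05), Gca (-1.29 ± 0.18, adjusted p = 9e-04), Fap (-3.43 ± 0.63, adjusted p = 0.019) and the adaptor Efs (-2.09 ± 0.43, adjusted p = 0.046). Rnd3, Kif5c, Gca and Fap lie within 20 Mb of Ifih1, and a direct effect of MDA5 loss on them was not tested. Of 15 alternative runs, Cxcr5 lost its call in 2 (voom and the deposited values, adjusted p up to 0.457), Fap in 7, Gimap3 in 8 and Dtx1 and Efs in 9, and the other named genes in 0. Samhd1 did not differ past the test (0.13, adjusted p = 0.94).

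B cell markers were higher in SAMHD1 MDA5 DKO than in SAMHD1 RIG-I DKO (median 2.51, adjusted p = 5.19e-10, adjusted p = 0.131 with an estimated correlation), 8 when adjusted over the list alone and 1 over all genes, with Pax5 at 3.71 ± 0.76, Ighm 3.56 ± 0.79 and Blk 2.59 ± 0.78. T cell markers (median 1.64, adjusted p = 0.000102, adjusted p = 0.146 with an estimated correlation) included Cd4 at 2.34 ± 0.68, and mast cell markers (median 2.50, adjusted p = 5.12e-07, adjusted p = 0.126 with an estimated correlation) Tpsb2 at 3.53 ± 0.79. Neutrophil and eosinophil markers were lower (median -0.734, adjusted p = 0.00188, adjusted p = 0.0427 with an estimated correlation), with Mmp8 (-2.04 ± 0.59) and Ccr3 lower when adjusted over the list alone. MHC class II genes had a median of 0.625 (adjusted p = 0.00232, adjusted p = 0.598 with an estimated correlation), and 0.129 without SAMHD1 MDA5 DKO library 1 (adjusted p = 0.391). Ccr7 (2.97 ± 0.68) was higher when adjusted over the dendritic cell list alone. In a fit of these 2 genotypes alone 94 genes were called, and voom called 11.

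In MDA5 KO against WT (n = 4 and 5), 9 genes were called, 4 higher and 5 lower. Of the 8 other than Ifih1, 6 lay within 20 Mb of it, where 0.068 were expected, and a direct effect of MDA5 loss on those was not tested. Ifih1 fell by 8.68 ± 0.47 on the log2 scale (adjusted p = 8.8e-11). Rnd3 rose from 885 ± 82.1 normalized counts to 4677 ± 1700 (2.34 ± 0.19, adjusted p = 1.3e-07), Dynlt1b rose 2.19-fold (1.13 ± 0.17, adjusted p = 0.0034), and ENSMUSG00000098320, which has no symbol, rose (2.64 ± 0.32, adjusted p = 0.00013), as did 1700016A09Rik. Kif5c was 10.5-fold lower (-3.39 ± 0.42, adjusted p = 0.00013). Rprm, linked to cell cycle arrest (-3.17 ± 0.55, adjusted p = 0.012), Gca (-1.07 ± 0.18, adjusted p = 0.0074) and Cytip (-0.42 ± 0.07, adjusted p = 0.012) fell. Of 17 alternative runs, the call was lost in 1 for Dynlt1b, 2 for Kif5c and Gca, 4 for Cytip, 6 for Rprm, 11 for 1700016A09Rik and 0 for Ifih1 and Rnd3. Samhd1 (0.15, adjusted p = 0.97) and Ddx58 (-0.27 ± 0.11, adjusted p = 0.85) did not pass.

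Interferon-stimulated genes were also lower in MDA5 KO than in WT, negative in 43 of 44 members (median -0.285), with 0 passing in limma over all genes or adjusted over the list alone; leaving out 1 library gave 0 to 12 over the list alone. Lgals3bp was 1.42-fold lower and Slfn5 1.3-fold lower. The list passed camera (adjusted p = 3.46e-15) but had an adjusted p = 0.446 with an estimated correlation. Inflammatory and NF-kB target genes had a median of -0.218 (adjusted p = 0.00307, adjusted p = 0.446 with an estimated correlation), with Nfkbia at -0.24 ± 0.32 and Socs3 at -0.23 ± 0.21, and proliferation genes -0.455 (adjusted p = 0.00526, adjusted p = 0.837 with an estimated correlation). Both lists lost their call without single libraries, at the highest with an adjusted p = 0.0561 and 0.591. Of the 9 genes, 7 were among the 8 called within the main run of library codes, where the interferon-stimulated list had an adjusted p = 1.53e-15. A fit of these 2 genotypes alone called 2.

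**Figure D4:**
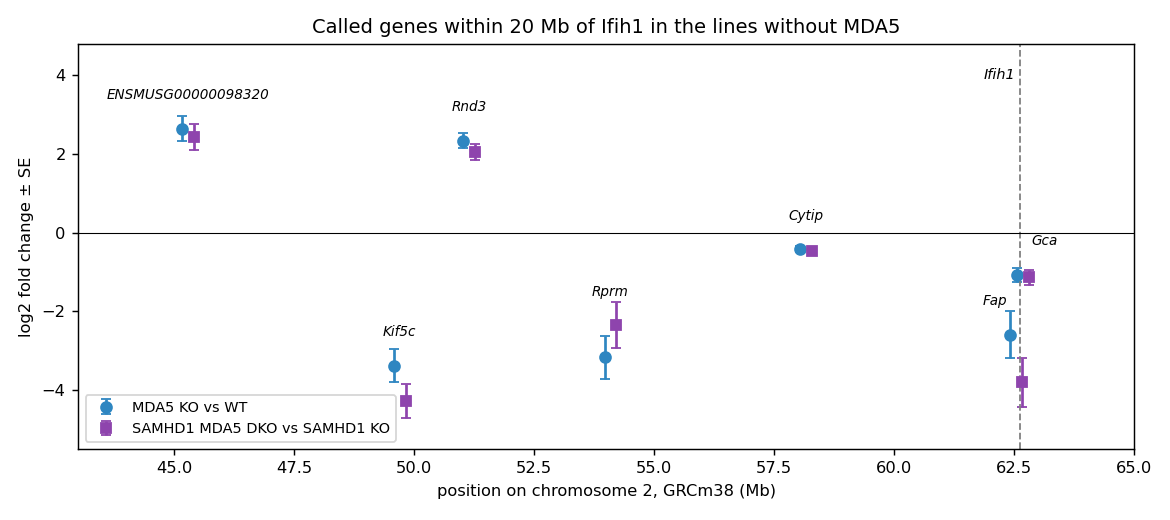
Log2 fold change ± SE of the 7 called genes within 20 Mb of Ifih1 against their position on chromosome 2 (Mb, GRCm38), in MDA5 KO against WT and SAMHD1 MDA5 DKO against SAMHD1 KO. Rnd3 is higher (2.34 and 2.06) and Kif5c lower (-3.39 and -4.28) in both comparisons.

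Genes of lymphocytes and mast cells were lower in RIG-I KO than in WT (n = 4 and 5), but their lists did not hold with an estimated correlation. The B cell score of WT library 3 (3.858) also lay near those of RIG-I KO (3.0302 to 3.3355). Genotype runs with the library codes, so an effect of RIG-I cannot be told apart from whatever the codes stand for. The immunoglobulin heavy chain Ighm fell from 926.7 ± 536 normalized counts to 28.1 ± 9.99 (-4.52 ± 0.75, adjusted p = 0.0058) and Spib from 63.3 ± 37.7 to 1.99 ± 2.65 (-4.35 ± 0.69, adjusted p = 0.0058). Dtx1 fell (-3.84 ± 0.59, adjusted p = 0.0051), and Ddx58 was 7.51-fold lower (-2.91 ± 0.11, adjusted p = 1.8e-14). Sez6l2 rose from 7.76 ± 3.77 to 22.8 ± 5.85 (1.54 ± 0.38, adjusted p = 0.026), as did Gm14418. Ighm and Spib were not called with voom or in a fit of these 2 genotypes alone (adjusted p up to 0.0894 and 0.0642), Dtx1 not in the latter, and Sez6l2 lost its call in 7 of 17 alternative runs. Samhd1 (0.03) and Ifih1 (-0.23, adjusted p = 0.8) did not pass. In all, 558 genes were called, 165 higher and 393 lower, with 12 and 65 of them at least 2-fold.

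B cell markers had a median of -3.53 in RIG-I KO against WT (adjusted p = 2.73e-09, adjusted p = 0.15 with an estimated correlation), 9 of 10 lower when adjusted over the list alone and 8 over all genes, including Pax5 (-4.33 ± 0.72) and Cd79a (-2.80 ± 0.55). Mast cell markers had -3.36 (adjusted p = 1.27e-05, adjusted p = 0.15 with an estimated correlation), 5 lower when adjusted over the list alone and 4 over all genes, including Cma1 (-3.36 ± 0.69), Tpsb2 (-3.46 ± 0.75) and Kit (-2.75 ± 0.65). T cell markers had -1.64 (adjusted p = 0.0154, adjusted p = 0.487 with an estimated correlation), with Tcf7 (-1.87 ± 0.56) and Cd4 (-1.83 ± 0.64) among 5 lower when adjusted over the list alone; without WT library 5 the adjusted p was 0.0707. Large peritoneal macrophage markers had -0.231 (adjusted p = 0.0397, adjusted p = 0.487 with an estimated correlation), with Selp (-0.39 ± 0.09), the macrophage receptor Adgre1 (-0.43 ± 0.13) and Fn1 (-0.46 ± 0.16) among 4 lower; without RIG-I KO library 1 the adjusted p was 0.0714. The interferon-stimulated list did not pass (median -0.0398, adjusted p = 0.487).

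Single members of other lists passed in RIG-I KO when adjusted over their lists alone. Lower were Flt3 (-2.89 ± 0.69) and Ccr7 (-2.47 ± 0.65) of dendritic cells, Tlr9 (-2.30 ± 0.75), Tapbp (-0.51 ± 0.12), Tnfaip3 (-0.65 ± 0.21), Nfkb1 (-0.28 ± 0.07) and Nfkb2 (-0.39 ± 0.10). Dtymk (0.55 ± 0.15) and Nme1 (0.54) of dNTP metabolism were higher. The B cell score was 3.15 ± 0.14 in RIG-I KO and 3.24 ± 0.20 in SAMHD1 RIG-I DKO, against 6.35 ± 1.44 in WT. The mast cell score was 0.73 ± 0.86 and 0.83 ± 0.74 in the lines without RIG-I, against 3.93 ± 1.48 in WT.

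Genes that differed in the lines without RIG-I overlapped with and without SAMHD1. Between RIG-I KO against WT and SAMHD1 RIG-I DKO against SAMHD1 KO, which share no library, 90 genes were higher in both, where independent lists would share 9.28, and 201 were lower in both, where they would share 19.1. The lists are not independent, since the fit gives each gene 1 variance for both comparisons. WT and SAMHD1 KO also each hold 1 library apart on the first component. The overlap was not tested without those 2 libraries. RIG-I KO against WT gave 2087 called genes within the main run of library codes, 557 of them shared, and the interferon-stimulated list had an adjusted p = 0.677. A fit of these 2 genotypes alone called 1 gene, and leaving out 1 library gave between 78 and 1253. All genotypes share 1 variance per gene in the fit of all 25 libraries. Replicates differed more in WT (chi-square per degree of freedom 32.96 to 217.5) than in RIG-I KO (13.55 to 25.67). The shared variance may be too small for RIG-I KO against WT. Whether it accounts for the calls was not tested.

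**Figure D5:**
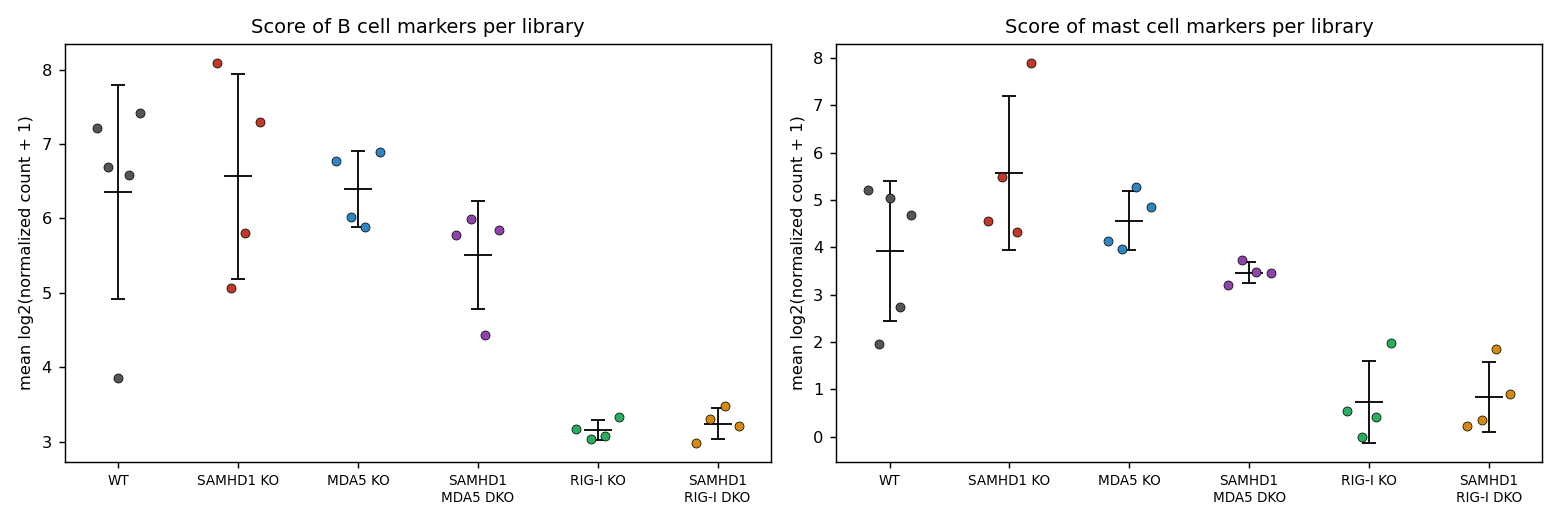
B cell and mast cell marker scores (mean log2 of normalized count + 1), with 1 point per library, grouped by genotype, and bars for mean ± SD. B cell scores are 3.15 ± 0.14 in RIG-I KO and 3.24 ± 0.20 in SAMHD1 RIG-I DKO, against 6.35 ± 1.44 in WT.

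Of the other lists, interferons and their receptors (adjusted p from 0.487 to 0.929), small peritoneal macrophage and monocyte markers (0.302 to 0.972) and erythroid genes (0.374 to 0.949) passed camera in none of the 10 comparisons. NK cell (0 of 8) and mesothelial and fibroblast markers (0 of 11) had no measured member.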

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

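All tests of the intermediate Samhd1 values, the B cell tests and all tests of genes near Ifih1 were chosen after the results were seen, as were the fits without doubted libraries; the splits of libraries and the transcript length test were set before.

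A library lying far from the others of its genotype was found for 16 of 210 groups examined, where chance gives about 1 in 20, or 10.5. Samhd1 was high in SAMHD1 KO library 2 (4767 normalized counts, nearest 1566) and in SAMHD1 MDA5 DKO library 3 (4952, nearest 1397). SAMHD1 MDA5 DKO library 1 was high for Irf7 (3183), Ifi44 (122.7) and Ifi206 (312.9), and for the scores of interferon-stimulated genes (10.08), GTPases (11) and MHC class I genes (13.52). SAMHD1 MDA5 DKO library 4 was low for interferons and receptors (11.61), and SAMHD1 MDA5 DKO library 2 for dNTP metabolism (9.002). RIG-I KO library 1 was high for proliferation (8.489) and dNTP metabolism (9.341). B cell scores were low in WT library 3 (3.858) and SAMHD1 MDA5 DKO library 3 (4.428), and the neutrophil and eosinophil score in SAMHD1 RIG-I DKO library 1 (6.53). WT library 3 lay at -50.89 on the first principal component.

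The effect of SAMHD1 loss differed with MDA5, by the interaction term and camera, for median log2 terms of 0.3844 in GTPases (adjusted p = 0.000341), 0.2444 in MHC class I (0.00092), 0.594 in MHC class II (1e-04), 0.7555 in proliferation (4.89e-06), 0.1507 in dNTP metabolism (0.0141) and -1.163 in B cell markers (0.00582). Each of these was lost, with an adjusted p = 0.533 with an estimated correlation. Without SAMHD1 MDA5 DKO library 1 the terms were -0.0503 in GTPases (0.988), 0.0501 in MHC class I (0.517) and 0.283 in MHC class II (0.0321). Mast cell markers (-2.784, adjusted p = 2.04e-06) and dendritic cell markers (-0.9749, 0.0242) were lost as well, with an adjusted p = 0.171 with an estimated correlation. With RIG-I the terms were 0.2286 in MHC class I (0.00205), 0.3803 in MHC class II (0.00909), 0.9513 in proliferation (4.81e-07), 0.1361 in dNTP metabolism (0.034) and -1.42 in mast cell markers (0.00841), all lost with an adjusted p = 0.642 with an estimated correlation. The term of -0.5208 in dissociation genes (0.00264) was lost with an adjusted p = 0.492 with an estimated correlation. When single libraries were left out, 5 of 8 calls with MDA5 and 5 of 6 with RIG-I were lost. Proliferation kept both, with medians from 0.385 to 1.42 with MDA5 and 0.566 to 1.63 with RIG-I. The highest adjusted p with MDA5 was 0.445 for B cell (-0.459), 0.181 for dendritic cell and 0.166 for dNTP genes. With RIG-I it was 0.344 for mast cell (-0.741), 0.0925 for MHC class I (0.126), 0.137 for MHC class II, 0.304 for dNTP and 0.0505 for dissociation genes (-0.365). The authors' deposited table also holds comparisons of the double knockouts with WT, which called 233 genes for SAMHD1 MDA5 DKO and 2131 for SAMHD1 RIG-I DKO at an adjusted p under 0.05.

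Other splits of the libraries tested each count. Few splits gave as many calls for MDA5 KO against WT (9 genes, highest other split 3, 1 of 100 splits as large with the real one) and RIG-I KO against WT (558, highest other 1040, 2 of 100). The same held for SAMHD1 MDA5 DKO against SAMHD1 KO (16, highest other 0, 1 of 35) and SAMHD1 RIG-I DKO against SAMHD1 KO (1388, highest other 5, 1 of 35). It held as well for SAMHD1 RIG-I DKO against RIG-I KO (9, highest other 0, 1 of 35) and between the double knockouts (21, highest other 0, 1 of 35). A split that mixes genotypes no longer separates the targeted gene, which favours the real split. The shares were not adjusted over comparisons, and genotype runs with the library codes. These counts therefore exclude neither chance nor whatever the codes stand for. Nor was chance excluded for SAMHD1 KO against WT (2 genes), where 21 of 100 splits gave as many. The highest, 2783, set WT library 3 with SAMHD1 KO libraries 2, 3 and 4, so that both libraries with the last codes stood together, and 16 splits gave over 3 times the real count, which points to a structure of the samples; within the main run of codes the count was 1. It was not excluded for SAMHD1 MDA5 DKO against MDA5 KO either (1 gene, highest other 44, 9 of 35 splits). Both interaction counts were 0, so all 100 splits were as large, with a highest other of 345 for MDA5 and 1522 for RIG-I.

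Samhd1 lay about midway between lines with and without the gene in SAMHD1 KO library 2 and SAMHD1 MDA5 DKO library 3. Wild-type RNA mixed into the latter is argued against, since a share of 42.62% would bring 768.9 normalized counts of Ifih1 and the library had 11.05. The test cannot speak to RNA of MDA5 KO, which has Samhd1 (10780) but little Ifih1 (5.53). For a single intact copy of Samhd1, SAMHD1 KO library 2 reached 84.9% of the midpoint of 5615, within the spread of WT (23.15%). WT library 5, with 6486 counts, also lies within that spread of the midpoint. The test therefore cannot speak for a single copy, which stays open. For SAMHD1 MDA5 DKO library 3, at 82.13% of its midpoint, the spread of MDA5 KO (15.2%) leaves a single copy open as well. Wild-type RNA in SAMHD1 KO library 2 stays open, because its interferon score of 10.01 lies near both the 9.932 of such a mixture and the 10.12 ± 0.29 of the other libraries. The library also carries the last code and stood apart on the first principal component, and no biological explanation in the design was tested.

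Many genes were called in the lines without RIG-I. A trend with transcript length is argued against as the whole cause, since 979 of the 1388 genes of SAMHD1 RIG-I DKO against SAMHD1 KO were still called after it was removed. Fold changes fell with length there (Spearman correlation -0.2975), and removal of the trend left 572 higher and 723 lower genes, against 745 and 643 before. Genes higher in both comparisons had a median exon length of 2.718 kb, against 4.247 kb for genes not called. A part played by length stays open for them. Over 17 libraries of the other genotypes, genes at least 2-fold lower in both comparisons followed the B cell score. Their median correlation was 0.8387, against 0.0196 for genes not called, and 0.7852 without the 2 libraries of the last codes. Fewer B cells may therefore account for part of these genes. Of these 52 genes, 8 members of the B cell list were left out. Among the other 44, 37 had a correlation over 0.5 over the 17 libraries. So did 67 of the 90 higher genes, which fewer B cells would not raise. That cut therefore does not single out B cell genes. The 149 genes lower by less than 2-fold did not follow it (-0.06679, and -0.1139 without the 2 libraries), and the 90 higher genes had the sign that fewer B cells would have lowered, at 0.651 but only 0.2721 without the 2 libraries (positive in 86.67% of them), so B cells are argued against for both. An effect of RIG-I itself on the macrophages remains untested, and since library codes run together within a genotype, genotype cannot be told apart from whatever the code stands for, which is not stated.

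Of the 17 genes called in the lines without MDA5 apart from Ifih1, 7 lay within 20 Mb of it, where 0.145 was expected by chance (permutation p = 1e-05, the smallest possible). A chromosome segment carried along with the targeted allele may account for these genes, which are Rnd3, Kif5c, Gca, Fap, Rprm, Cytip and ENSMUSG00000098320. Reads running out of the altered locus are argued against for 5 of them, the nearest 4.459 Mb from Ifih1, and stay open for Gca and Fap, the 2 called genes within 0.1 Mb. A direct effect of MDA5 loss on these genes was not tested.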

How the results depend on the processing

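The variance-stabilized values as deposited, voom, both fits without doubted libraries and the lists with each library left out were chosen after the data were seen; the other alternatives were planned. Without a low-count filter and with a pseudocount of 0.1, all 10 counts of called genes stayed within 1.5 times. Why counts moved was not tested. Fits of the compared genotypes alone hold fewer libraries, yet some counts rose in them.

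SAMHD1 KO against WT had 2 called genes, and 4 with quantile normalization, 5 with the deposited variance-stabilized values, 5 with voom, 1 with only these genotypes, 1 without the libraries apart on the first component, 6 at an adjusted p under 0.1 and 26 in the authors' table. MDA5 KO against WT had 9, with 2 in only these genotypes and 21 in the authors' table. RIG-I KO against WT had 558, with 1 in only these genotypes, 2087 (1041 higher and 1046 lower) without the libraries apart, 1583 at 0.1 and 1174 in the authors' table. SAMHD1 MDA5 DKO against SAMHD1 KO had 16, with 4 in only these genotypes, 534 without the libraries apart, 6 without those of intermediate Samhd1, 8 with voom, 932 at 0.1 and 878 in the authors' table. SAMHD1 RIG-I DKO against SAMHD1 KO had 1388, with 546 in only these genotypes (376 higher and 170 lower), 2122 without the libraries apart, 548 (156 of them higher) without those of intermediate Samhd1 and 2441 at 0.1. SAMHD1 MDA5 DKO against MDA5 KO had 1, with 2 after quantile normalization, 0 in only these genotypes, 9 without the libraries of intermediate Samhd1 and 5 at 0.1. SAMHD1 RIG-I DKO against RIG-I KO had 9, with 68 in only these genotypes and 15 at 0.1. The double knockouts had 21 between them, with 11 from the deposited values, 94 in only these genotypes, 11 with voom and 32 at 0.1. Both interactions had 0 in limma and in each alternative run.

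The interferon-stimulated list lost its call with an estimated correlation in MDA5 KO against WT (adjusted p = 0.446, fry 0.499), SAMHD1 MDA5 DKO against SAMHD1 KO (0.674, fry 0.117) and between the double knockouts (0.146, fry 0.0654). Its direction in SAMHD1 RIG-I DKO against SAMHD1 KO, which never passed, reversed with fry (0.978), without the libraries apart (0.995) and without those of intermediate Samhd1 (0.97), and its score to -0.0155 in both of these fits; the cause was not tested. With the median over members the score difference of SAMHD1 MDA5 DKO against MDA5 KO was 0.422 (exact permutation p = 0.0857) and that between the double knockouts -0.367 (0.0286).

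Leaving out 1 library at a time gave 0 to 9 genes in SAMHD1 KO against WT, with 0 without SAMHD1 KO library 3 or 4 or WT library 2, 1 without WT library 4, 4 without WT library 1, 5 without SAMHD1 KO library 1, 8 without WT library 5 and 9 without WT library 3. MDA5 KO against WT ran from 6 to 10. RIG-I KO against WT ran from 78 to 1253, with 81, 78, 138 and 176 without RIG-I KO libraries 1, 2, 3 and 4, and 210, 1253 and 148 without WT libraries 2, 4 and 5. SAMHD1 MDA5 DKO against SAMHD1 KO ran from 8 to 43, with 8, 32 and 10 without SAMHD1 MDA5 DKO libraries 2, 3 and 4, and 33, 10 and 43 without SAMHD1 KO libraries 1, 2 and 3. SAMHD1 RIG-I DKO against SAMHD1 KO ran from 188 to 1418, with 431, 188 and 486 without SAMHD1 RIG-I DKO libraries 1, 2 and 4, and 531 without SAMHD1 KO library 2. SAMHD1 MDA5 DKO against MDA5 KO ran from 0 to 8, with 4 without MDA5 KO library 1, 8 without SAMHD1 MDA5 DKO library 3, and 0 without MDA5 KO library 3 or 4 or SAMHD1 MDA5 DKO library 1, 2 or 4. SAMHD1 RIG-I DKO against RIG-I KO ran from 0 to 10, with 4, 2 and 3 without RIG-I KO libraries 1, 2 and 4, and 4, 2, 1 and 0 without SAMHD1 RIG-I DKO libraries 1, 2, 3 and 4. Between the double knockouts it ran from 10 to 18, with 13 and 12 without SAMHD1 MDA5 DKO libraries 1 and 2, and 12 and 10 without SAMHD1 RIG-I DKO libraries 1 and 4. Both interactions stayed at 0.

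For the interferon-stimulated list the adjusted p ran, in the same order, from 6.1e-55 to 4.54e-23, 1.78e-27 to 5.69e-08, 0.0383 (without WT library 2) to 0.972, 8.77e-15 to 0.00188, 0.171 to 0.96, 4.13e-45 to 6.37e-26, 5.35e-71 to 4.03e-53 and, between the double knockouts, 1.25e-29 to 4.62e-09. Its MDA5 interaction ran from 0.00073 to 0.949 and its RIG-I interaction from 0.00371 to 0.953. Directions reversed in SAMHD1 RIG-I DKO against SAMHD1 KO without SAMHD1 RIG-I DKO library 4 (0.799) or SAMHD1 KO library 1 (0.457) or 2 (0.96), in the MDA5 interaction without MDA5 KO library 1 (0.585), SAMHD1 MDA5 DKO library 3 (0.942) or 4 (0.949), SAMHD1 KO library 3 (0.557) or WT library 2 (0.673), and in the RIG-I interaction without SAMHD1 KO library 1 (0.953). Score differences ran from 0.578 to 0.773 in SAMHD1 KO against WT, -0.574 to -0.329 in SAMHD1 MDA5 DKO and -0.0713 to 0.12 in SAMHD1 RIG-I DKO against SAMHD1 KO, 0.508 (without SAMHD1 MDA5 DKO library 1, exact permutation p = 0.0571) to 0.742 and 0.737 to 0.871 against the sensor knockouts, and -0.587 to -0.388 between the double knockouts.

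Of 62 list calls by camera, 29 held whichever library was left out and 33 did not. Without SAMHD1 MDA5 DKO library 1 the median of MHC class I genes in SAMHD1 MDA5 DKO against SAMHD1 KO reversed to -0.0199 (adjusted p = 0.902) and the MDA5 interaction of GTPases to -0.0503 (0.988), and camera put MHC class II genes of SAMHD1 MDA5 DKO against MDA5 KO down (mean -0.0223, 0.905); the cause was not tested.

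Of 72 calls of 52 named genes, counted per comparison, none reversed in any alternative run. Calls were lost for 26 in fits of only the compared genotypes, 17 with voom, 7 with the deposited values, 7 and 3 without doubted libraries, 4 with quantile normalization and 3 with the pseudocount of 0.1, and in 156 tests that left out 1 library, against 440 that kept the call. No paired analysis was possible because the columns carry no replicate numbers and cannot be matched to single titles. The edgeR and DESeq2 alternatives were not run, because the design set limma for values deposited as normalized. They could have been run on the recovered whole reads, on which voom was run. In simulated data for SAMHD1 KO against WT, 46.3% of 1.5-fold changes were recovered, which limits what small changes could be seen.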

Other observations

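Irf7 ordered the 6 genotypes as the interferon-stimulated score did, except that SAMHD1 KO and SAMHD1 RIG-I DKO changed places. Irf7 is 1 of the 44 members of that score, so the shared order is in part built in. Its normalized counts were 1237 ± 329 in MDA5 KO, 1499 ± 149 in RIG-I KO, 1780 ± 465 in WT, 2270 ± 613 in SAMHD1 MDA5 DKO, 3518 ± 266 in SAMHD1 RIG-I DKO and 4402 ± 1290 in SAMHD1 KO (SD, n = 5 for WT and 4 for the others). The score of the list was 9.01 in MDA5 KO and 9.66 in SAMHD1 MDA5 DKO, 9.41 in WT and 10.09 in SAMHD1 KO, and 9.32 in RIG-I KO and 10.11 in SAMHD1 RIG-I DKO. In the authors' deposited table, 9 of the 44 list members were higher in SAMHD1 KO against WT, 12 were lower in SAMHD1 MDA5 DKO against SAMHD1 KO, and against WT 0 were higher in SAMHD1 MDA5 DKO and 22 in SAMHD1 RIG-I DKO.

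Markers of cells other than macrophages varied between the lines with RIG-I. B cell scores were 6.56 ± 1.38 in SAMHD1 KO, 6.39 ± 0.51 in MDA5 KO and 5.51 ± 0.73 in SAMHD1 MDA5 DKO, and mast cell scores 5.57 ± 1.63, 4.56 ± 0.62 and 3.46 ± 0.22. Dendritic cell scores were 4.56 ± 0.69 in WT, 2.76 ± 0.41 in RIG-I KO and 2.72 ± 0.41 in SAMHD1 RIG-I DKO, and T cell scores 4.15 ± 0.92, 2.79 ± 0.34 and 2.95 ± 0.18. Fap, chosen after its values were seen, had a log2 fold change of -2.60 ± 0.60 in MDA5 KO against WT that did not pass (adjusted p = 0.24). Near Ddx58, 3 genes within 20 Mb were called in RIG-I KO against WT, where 6.81 were expected, and 22 in SAMHD1 RIG-I DKO against SAMHD1 KO, where 17 were expected.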
